A study of Caenorhabditis elegans with 2 samples.

How the data were processed

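Each of the 2 samples is a ChIP-seq library from whole late embryos, labelled with an age of 2 hours, of a C. elegans strain whose ceh-45 gene carries a GFP and epitope tag inserted by genome editing. Per the labels' protocols, embryos were collected by bleaching, chromatin was sonicated, the precipitation used an antibody against GFP (another label field gives ceh-45 as the antibody), and fragments were selected at 200 to 800 bp. The labels name the 2 samples as separate biological replicates of one strain and stage, and they form the single group.

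The authors deposited peak lists in narrowPeak form on build ce11. Per the files deposited with them, the lists were made from the alignments of the replicates and a control file, and peaks were ranked by the irreproducible discovery rate (IDR), the expected share of irreproducible peaks at a given rank. The aligner and the peak caller are not given in the sources used here, and the control is not analysed here. For the series there are 2 pairs of lists, each a ranked list of candidates and a thresholded set, with a larger and a conservative version; each replicate has such a pair of its own. The signal of a peak is the authors' deposited value, and its relation to depth or control is not stated. The deposited lists also give the −log10 of the global IDR, which reaches at most 5. All peaks of the thresholded sets had a global IDR of at most 0.01 in their ranked list; 124 peaks of the larger list with such a value are absent from its thresholded set, and 118, 88 and 102 in the conservative, replicate 1 and replicate 2 lists. The thresholded sets list a further input that the deposited notes do not describe. IDR picks peaks that repeat between the lists compared, so regions that are enriched in every library for any reason are favoured. Only the conservative version is tied by its columns to a comparison of the 2 replicates. For the larger version and for each replicate's own lists, the columns used here do not show what was compared. No list gives read counts, so depth is unknown, and intervals cover counting error over peaks only. The ranked list of the conservative version holds the signals of both replicates without saying which is which, so these were used as an unordered pair. No column of per-sample values was left unmapped.

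Chromosome lengths of the reference genome WBcel235, which has ce11 coordinates, held all ranked peaks. Genes, transcripts and biotypes came from Ensembl release 115 (19973 nuclear protein-coding genes and 1107 tRNA, snRNA, snoRNA and rRNA genes), and tRNA products and tRNA pseudogenes from the RefSeq annotation of the same assembly, which named a product for 607 of 612 nuclear tRNA genes. Passing peaks were those of the larger thresholded set (548). The background was the 108212 ranked candidates with an IDR above 0.01 that overlap no passing peak. Overlap means at least 1 bp. A promoter runs from 500 bp upstream to 100 bp downstream of an annotated transcript start of a protein-coding gene, a peak was assigned to every protein-coding gene with the summit from 2000 bp upstream to 500 bp downstream of a start, and a peak was near a small RNA gene within 250 bp.

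Shares were compared with two-sided Fisher's exact tests. Motifs on either strand were sought in the 101 bp around the summit and in a window of the same width centred 300 bp to its lower-coordinate side, with an exact McNemar test over the peaks, two-sided for the 9 fixed motifs and one-sided for the 2080 words of 6 bases (a word and its reverse complement counted as one). P-values were adjusted by Benjamini-Hochberg within each family with a threshold of 0.05. Intervals of shares are exact 95% binomial intervals. Chance overlap came from 1000 random circular shifts, correlations from 100000 permutations, and the copy number of sequence from the share of 31-base words that occur more than once in the assembly, in 201 bp around a summit or over a tRNA gene. Dinucleotide-preserving shuffles (500) of the summit windows gave the expected number of words. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

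The groups, tests, alternatives, gene lists, motifs and the rule for naming genes were fixed before the data were examined. The rule names ceh-45, the genes assigned to the 20 peaks of highest signal among those overlapping both replicates' own sets, the 4 members with the highest-signal peak of each list past the threshold and of the homeobox and panneuronal lists, and the 2 strongest peaks of each replicate's own set that the other lacks. Other genes named were chosen after their values were seen: W03C9.9, C51F7.3, C51F7.4, rpr-1, the genes whose introns hold a peak, the tRNA and snRNA genes at peaks, and those in the closing observations. Of the names on the lists, nca-1, tni-2, rpa-0 and daf-21 are not symbols of this annotation and were not counted.

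Alternatives fixed in advance were the conservative set, a global IDR of at most 0.01, each replicate's own lists (leaving out the other replicate), the next 2000 candidates in rank or random positions (20 per peak) as background, other overlap rules, windows (51 and 201 bp), flanks, promoter limits and assignments, a longer TAATCCB motif, and a distance of 100 bp to RNA genes. The limit of 0.01 removed no peak and tests nothing. Added after the data were seen were an IDR of at most 0.001, the peaks away from small RNA genes, and a background matched on GC content (2732 candidates, 5 per peak; 2 GC values had fewer). The tests of motifs, 6-base words and gene lists were tried on simulated data: with nothing planted, none of 20 draws called TAATCC among 9 motifs or among 2080 words, nor the ribosomal protein list among 25. With TAATCC planted in 5% of 548 windows, 14 draws recovered it as a motif and 2 in the scan of words. With 10%, all 20 did in both. These windows were the 2 flanks of candidates with an IDR above 0.01, so no GC difference between summit and flank was simulated. With 4 ribosomal protein peaks added to 548, no draw called the list, and with 8 all 20 did.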

Results

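Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where CEH-45 lies on the genome of the nematode Caenorhabditis elegans in late embryos. CEH-45 is a homeodomain protein of the goosecoid class, and proteins of this class are known to bind the core sequence TAATCC. The worms came from a strain in which the ceh-45 gene carries an insertion that adds GFP and epitope tags, and chromatin was precipitated through the GFP tag from whole embryos obtained by bleaching. The series holds 1 group of 2 biological replicates and no second condition, so its comparisons are between the replicates and between sites that passed the authors' reproducibility threshold and candidate sites that did not. The peak lists give no read counts, so the depth of each library is unknown. Positions are on build ce11, and each signal is the authors' peak value, used within its own list.

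The first question was how many sites were called and whether they repeated. The larger reproducible set of the series held 548 peaks, with a median width of 304 bp and a median signal of 80.1, out of 108916 ranked candidates. Some of these peaks overlap another passing peak and carry the same pair of replicate signals. The 548 are therefore intervals rather than separate sites, and such sites count more than once in the tests over peaks. A conservative set held 463 peaks, of which 404, or 87.3% (exact 95% interval 83.9 to 90.2), overlapped the larger set. The replicates' own sets held 258 peaks for replicate 1 and 227 for replicate 2, a mean of 242.5 ± 21.9 (SD, n = 2).

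Of the replicate 1 peaks, 151, or 58.5% (exact 95% interval 52.3 to 64.6), overlapped a replicate 2 peak by at least 1 bp, and 150 of the replicate 2 peaks, or 66.1% (59.5 to 72.2), overlapped a replicate 1 peak. Shifting the peaks at random along their chromosomes gave a mean overlap of 0.142% and 0.152%, with highest values over 1000 shifts of 11.6% and 1.76%. Where peaks of both replicates overlapped, their summits lay a median of 19 bp apart. In the larger set, 151 peaks overlapped a peak of both replicates' own sets, 166 overlapped one of these sets only, and 42.2% (exact 95% interval 38 to 46.4) overlapped neither.

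Across the 548 peaks, the log10 signals of the replicates correlated with a Pearson r of 0.52 and a Spearman rho of 0.48. Both permutation p-values were 1e-05, the smallest that 100000 permutations can give, and the correlation is across peaks, which are not independent replicates. The median absolute log2 ratio between replicates was 0.37. Over all 71732 ranked peaks of the conservative list, which holds these paired signals, r was 0.29. Without the 10 highest of the 548 peaks it was 0.44. In the conservative set it was 0.75, but that set was selected for agreement between the replicates, so a higher r there is partly built in. In the 196 peaks near genes of small noncoding RNAs r was 0.58, and in the other 352 it was 0.37; the difference between these values was not tested.

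**Figure D1:**
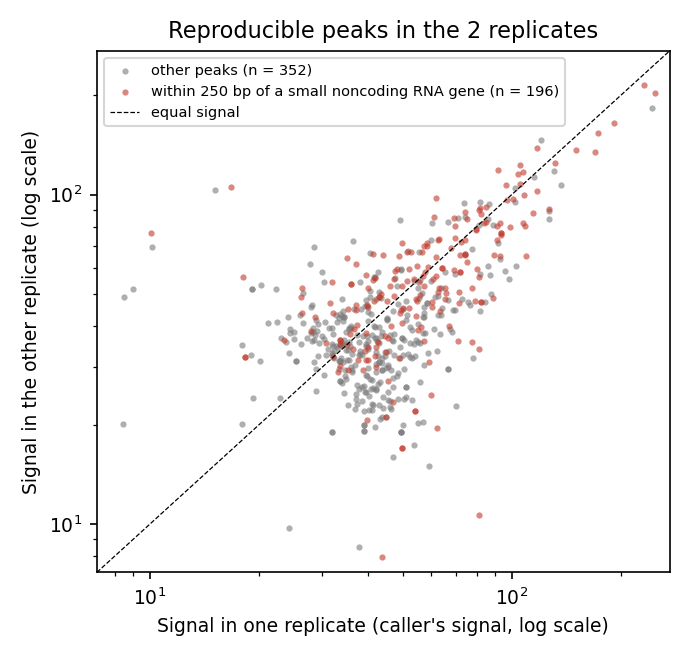
Signal of each of the 548 reproducible peaks in one replicate (x axis, log scale) against the other replicate (y axis, log scale). Red points are the 196 peaks within 250 bp of a tRNA, snRNA, snoRNA or rRNA gene, grey points the other 352, and the dashed line marks equal signal; the Pearson r of the log10 signals is 0.52.

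The next question was whether the tagged gene is itself a site. No passing peak lay within 5000 bp of ceh-45 (WBGene00022837, chromosome I, 1128324 to 1131765, plus strand) in the larger, the conservative or either replicate's own set. The larger list held 21 candidate peaks there. The candidate closest to the threshold covered 1131743 to 1132046, with its summit in the intergenic sequence just past the 3' end of the gene. Its signal was 43.6, above 96.0% of candidates or equal to them, and its irreproducible discovery rate was 0.0488, short of the limit of 0.01. In replicate 1 the candidate at this place had a signal of 34.3 and a rate of 0.201. In replicate 2 the candidate closest to the threshold lay beside it without overlap, at 1132095 to 1132370, with a signal of 25.9 and a rate of 0.305.

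**Figure D2:**
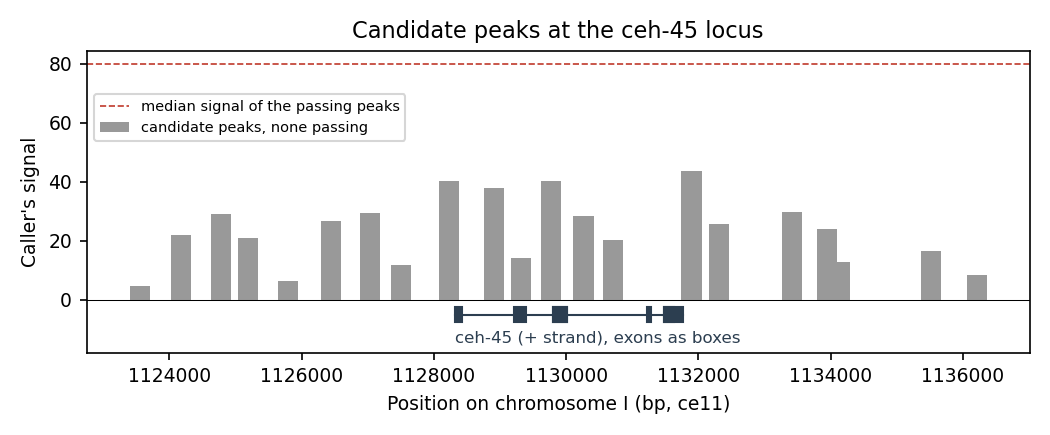
Candidate peaks of the larger list around ceh-45 on chromosome I (x axis, position in bp; y axis, the caller's signal), with the exons of the gene as boxes. None of the 21 candidates passed; the highest, at a signal of 43.6, lies past the 3' end, and the dashed line marks the median of 80.1 among passing peaks.

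Many of the sites lay beside genes of small structural RNAs. Of the 548 passing peaks, 196, or 35.8% (exact 95% interval 31.7 to 39.9), had their summit within 250 bp of a tRNA, snRNA, snoRNA or rRNA gene, against 0.714% of the 108212 candidates that did not pass. The odds ratio was 77.4 (two-sided Fisher's exact test, p = 4.89e-259). Transfer RNA genes lay near 26.3% of passing peaks and 0.381% of the others, and snoRNA genes, whose RNAs guide the modification of ribosomal and spliceosomal RNA, near 8.21% and 0.243% (adjusted p = 1.54e-203 and 1.58e-50 by Fisher's exact test with Benjamini-Hochberg adjustment over 9 biotypes). Spliceosomal snRNA genes lay near 1.46% and 0.0850% (adjusted exact p = 1.10e-07). No passing peak lay near an rRNA gene, which allows a share of up to 0.671% (exact 95% limit), and microRNA genes lay near 0.547% of passing peaks and 0.170% of the others (adjusted p = 0.119). The broad ncRNA biotype of the annotation lay near 28.6% of passing peaks and 4.86% of the others (odds ratio 7.86, adjusted exact p = 8.70e-73). The lincRNA, piRNA and pseudogene biotypes did not pass (adjusted exact p = 0.788, 0.119 and 0.143). Against the next 2000 candidates in rank the odds ratio was 13.0, and against candidates of the same GC content, a background chosen after the data were seen, it was 39.5. Peaks are the units of these tests and neighbouring peaks are not independent, so the p-values describe these lists and not a population of embryos.

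**Figure D3:**
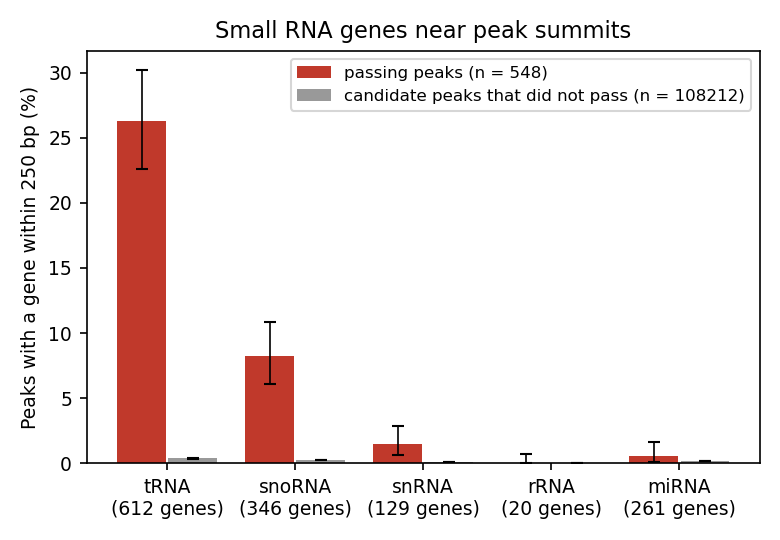
Share of peaks with a gene of each RNA class within 250 bp of the summit (y axis, percent; bars start at 0; error bars are exact 95% binomial intervals) for the 548 passing peaks and the 108212 candidates that did not pass. The tRNA bar stands at 26.3% for passing peaks and 0.381% for the others.

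The share near small RNA genes was higher among the strongest calls than among the weakest. It was 65.6% (exact 95% interval 57.4 to 73.1) among the 151 peaks found in both replicates' own sets and 18.2% (13.4 to 23.8) among those found in neither (Fisher's exact test, p = 6.07e-21). Among the 137 peaks with the highest signal it was 65.0%, and among the 137 with the lowest 19% (Fisher's exact test, p = 9.22e-15). These splits by strength were chosen after the data were seen.

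Of the 20 peaks with the highest signal among those found in both replicates, 13 lay near small RNA genes, 8 of them at snoRNA genes and 5 at tRNA genes. The highest, with a signal of 451, lay in intergenic sequence on chromosome II, 11960706 to 11960963, at the snoRNA gene W03C9.9; the protein-coding gene W03C9.2 was assigned to it. The next, with a signal of 444, lay on chromosome V, 12303535 to 12303757, in an intron of frm-7 that holds the snoRNA genes C51F7.3 and C51F7.4. Peaks in introns of pxn-1 (V, 8500485 to 8500679, signal 354) and cutl-18 (V, 11314132 to 11314263, signal 336) also lay at snoRNA genes. A peak of signal 258 on chromosome X, 13665524 to 13665605, lay at a tRNA-Leu gene, and one of signal 257 in an intron of sulp-3 (X, 8404478 to 8404593) lay at a tRNA-Asn gene. In an intron of ints-8, the peak at I, 13463826 to 13464129 (signal 240), lay at rpr-1, the gene of the RNase P RNA that processes tRNA precursors.

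Protein-coding genes were assigned to 8 of these 20 peaks. The third highest (III, 8043844 to 8044064, signal 429) was intergenic and was assigned to spcs-3, which encodes a subunit of the signal peptidase complex, K12H4.5 and K12H4.6. An intergenic peak at III, 10461286 to 10461406 (signal 266), had atx-2, the ataxin-2 homologue, and ecps-1 assigned to it. The intergenic peak at IV, 390429 to 390541 (signal 242), was assigned to ears-2, a mitochondrial glutamyl-tRNA synthetase gene, and uncp-18. M01F1.9 was assigned to a peak in an intron of M01F1.8 (III, 3499887 to 3500190, signal 215). The peaks of the other assigned genes lay at snoRNA genes: sre-23, a chemoreceptor gene (I, 8259480 to 8259631, intergenic, signal 294), T02E1.2 (I, 8224383 to 8224502, intergenic, signal 230) and mrps-28, a mitochondrial ribosomal protein gene (V, 19643076 to 19643379, in an intron of Y43F8C.7, signal 214). All 20 overlapped a passing peak of the conservative set.

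Sites found in 1 replicate's own set only were given for comparison. The strongest of replicate 1 lay at a tRNA-Lys gene on chromosome X, 12106057 to 12106356 (signal 137), and the second was an intergenic peak at II, 10248403 to 10248702 (signal 102.6), to which atad-3 and nrde-2, a nuclear RNA interference gene, were assigned. The strongest of replicate 2 were intergenic peaks with no assigned gene at I, 6772943 to 6773218 (signal 103.5), and V, 14756623 to 14756898 (signal 72.4). All of these except the tRNA-Lys peak were also in the larger reproducible set. The other replicate had candidates at the peak on II (signal 60.6) and at the peak on V (signal 36.3), so these are not sites of 1 replicate alone.

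Promoters of protein-coding genes also held more of the passing peaks than of the other candidates. Of the passing peaks, 31.9% (exact 95% interval 28.0 to 36) had their summit from 500 bp upstream to 100 bp downstream of an annotated transcript start, against 14.7% (14.5 to 14.9) of the other candidates (odds ratio 2.72, Fisher's exact test, p = 4.53e-24). Among the 352 peaks away from small RNA genes, a subset chosen after the data were seen, the share was 42.9%, with an odds ratio of 4.36. Against the next 2000 candidates in rank, 21% of which lay in promoters, the odds ratio was 1.76.

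By region, 8.94% of passing summits lay in exons of protein-coding genes and 31.9% of the others did, an odds ratio of 0.210 (adjusted p = 9.38e-37, Fisher's exact test with Benjamini-Hochberg adjustment over 4 classes). Introns held 34.1% and 33.4% (adjusted exact p = 0.716). Away from small RNA genes, a subset chosen after the data were seen, introns held fewer, 26.7% and 33.3% (odds ratio 0.728, adjusted exact p = 0.0103). Intergenic sequence held 42.9% and 30.8% (odds ratio 1.68, adjusted exact p = 4.37e-09). Genes of other biotypes alone held 14.1% and 3.92% (odds ratio 4.0, adjusted exact p = 2.55e-21). For these genes the odds ratio was 2.66 against the next 2000 candidates in rank (adjusted exact p = 3.09e-09). Away from small RNA genes it was 1.75 (adjusted exact p = 0.0169).

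The X chromosome held 22.6% of passing peaks and 17.4% of the other candidates (odds ratio 1.39, adjusted p = 0.0110, Fisher's exact test over 6 chromosomes). No other chromosome passed the adjusted threshold, and chromosomes IV and V both had an adjusted p of 0.0518 with odds ratios of 0.747 and 0.770. Against random positions both passed (odds ratios 0.676 and 0.708, adjusted exact p = 0.0106 each), and in replicate 1 alone V did (odds ratio 0.617, adjusted exact p = 0.0259). Without peaks near small RNA genes, a subset chosen after the data were seen, the direction turned: the X share was 15.6% against 17.3%, an odds ratio of 0.885 (adjusted exact p = 0.525). Of the 612 nuclear tRNA genes, 276 lie on X.

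The TAATCC core expected of a goosecoid-class homeodomain was not enriched at the summits. It stood in the window around 14 of 548 summits, or 2.55% (exact 95% interval 1.40 to 4.25), and in 25 flanks of the same peaks, or 4.56% (2.97 to 6.66). It was in the centre only at 11 peaks and in the flank only at 22 (exact two-sided McNemar test, p = 0.0801, adjusted p = 0.103 over 9 motifs). Among candidates that did not pass, 3.66% carried it (Fisher's exact test, p = 0.208). In the conservative set the share was 2.38% against 5.40% in the flank, a deficit past the threshold (exact McNemar test, adjusted p = 0.0226), and in replicate 2 alone it was 2.20% against 6.17% (adjusted p = 0.0404). Against the flank on the other side of the summit, where 2.74% of the 548 peaks carried the word, there was no such deficit (exact McNemar test, adjusted p = 1). When TAATCC was planted in 10% of simulated windows, all 20 draws recovered it, and at 5% 14 of 20 did. Both simulated windows were flanks of candidates with an IDR above 0.01. They lacked the GC difference between these summits (49.8%) and their flanks (36.2%), so recovery at the real summits may be lower.

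Other sequence words differed between summit and flank. The GC box GGGCGG stood at 8.03% of summits and in 1.64% of flanks (adjusted p = 1.63e-06), the GAGAGA repeat at 11.9% and 5.84% (adjusted p = 0.00101), and the E-box CANNTG at 34.5% and 26.6% (adjusted p = 0.0105; all exact McNemar tests). The GATA-factor site HGATAR was lower, at 12% and 24.3% (adjusted exact p = 1.19e-06), as was the homeodomain core TAATTA, at 0.912% and 4.93% (adjusted p = 3.39e-04). The forkhead site TRTTKRY (18.1% and 23%, adjusted exact p = 0.0736), TAATNNNATTA and TGACGTCA (each in 0% and 0.547%, adjusted exact p = 0.25) did not pass. TRTTKRY did pass, lower at the summit, against the 28.8% of the flank on the other side (adjusted exact p = 5.16e-05) and with a narrower window of 51 bp and a wider one (adjusted exact p = 0.0450 and 0.00800), and TAATNNNATTA did with the wider window (0% and 1.64%, adjusted exact p = 0.00703). Against flanks, GGGCGG and HGATAR passed in every peak set and with every window and flank run. Against the next 2000 candidates in rank HGATAR was the only motif to pass (18.2% of them, adjusted Fisher's exact p = 0.00557), while GGGCGG (5.4%, adjusted exact p = 0.112), TAATTA (2.3%, 0.116) and GAGAGA (10.4%, 0.452) did not. GAGAGA did not pass with 51 bp (5.11% and 3.28%, adjusted exact p = 0.236) or at an IDR of at most 0.001 (adjusted exact p = 0.110), nor TAATTA at that limit (adjusted exact p = 0.45) or away from small RNA genes (1.42% and 4.26%, adjusted exact p = 0.0745). The E-box call was lost in replicate 1 and replicate 2 alone (adjusted exact p = 0.116 and 0.0705), at an IDR of at most 0.001 (0.649), against the flank on the other side (adjusted exact p = 0.161) and against the candidates that did not pass, where 33.2% carried it (adjusted exact p = 0.524). Base composition moved with these words: the summit windows were 49.8% ± 8.18 GC (SD over 548 peaks) and their flanks 36.2% ± 9.58. Against candidates of the same GC content none of the 9 motifs passed after adjustment; the lowest adjusted p was 0.111, and 3 motifs had an unadjusted p under 0.05 (Fisher's exact test).

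In a scan of all 6-base words, 361 were more frequent at summits than in flanks (one-sided exact McNemar test, adjusted p under the threshold of 0.05), and 276 of them, or 76.5%, had at least 4 G or C bases. The leading word was CGAACC, at 14.2% of summits and 2.19% of flanks (adjusted exact p = 4.48e-11), followed by GTTCGA at 16.2% and 3.47% (adjusted p = 4.75e-10). GTTCGA is part of the B box, the internal promoter element of tRNA genes. TAATCC ranked 1731 in this scan. Among the 352 peaks away from small RNA genes, 118 words passed, led by GCGCAA at 10.5% and 0.568% (adjusted exact p = 1.87e-06).

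**Figure D4:**
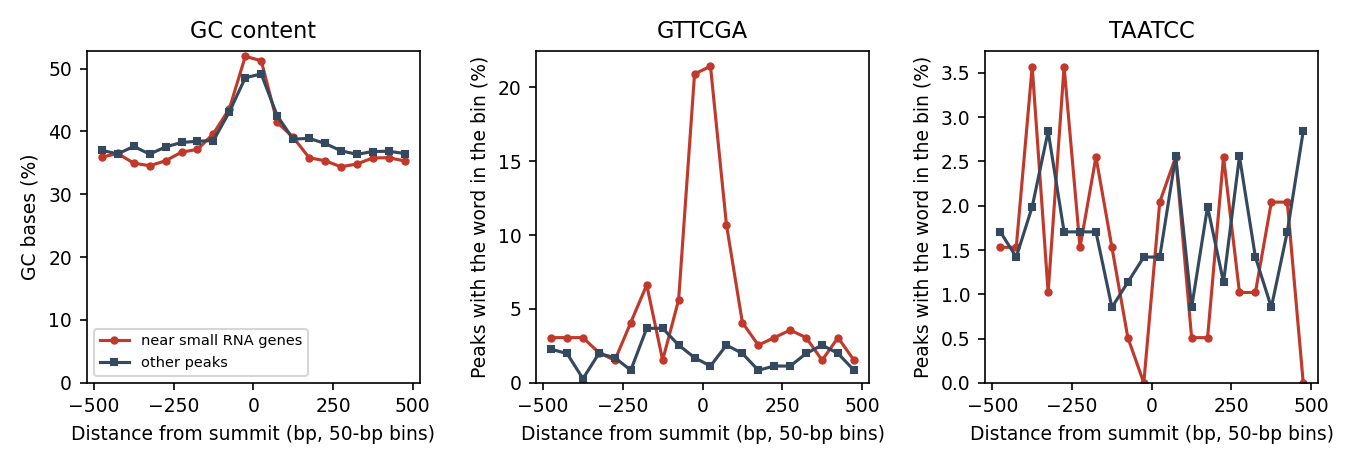
Mean GC content (left, percent) and share of peaks with GTTCGA (middle) or TAATCC (right) in 50-bp bins from 500 bp below to 500 bp above the summit, for the 196 peaks near small RNA genes (red) and the other 352 (blue). GC content peaks at the summit in both groups, GTTCGA reaches 21.4% only near small RNA genes, and TAATCC stays at or below 3.57% throughout.

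Genes near the peaks were then compared with 25 lists fixed before the data were examined. Protein-coding genes were assigned to 310 of the 548 peaks, or 56.6%, giving 429 genes. Peaks of 5 lists were more frequent among passing peaks than among the other candidates: ribosomal protein, mitochondrial respiration, histone, heat shock and chaperone, and ciliary genes. All 5 calls were lost against the next 2000 candidates in rank, where no list passed (4 had an unadjusted Fisher's exact p under 0.05). The odds ratios there were 1.83 to 3.67 apart from 9.20 for the ciliary list, which had 2 peaks in that background. Only the ribosomal protein list passed in both replicates' own sets. In replicate 2 alone the ciliary list passed too (odds ratio 11.0). The mitochondrial, histone and heat shock calls were lost there, at 3.39, 4.75 and 2.02. In replicate 1 alone these 3 were lost at 7.66, 5.83 and 4.51, and the ciliary call at 4.33. Against candidates of the same GC content, chosen after the data were seen, the ciliary and histone calls were lost at odds ratios of 3.14 and 6.69 (adjusted Fisher's exact p = 0.214 and 0.110), the histone list with 3 peaks in that background.

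Ribosomal protein genes had the lowest p-value of the lists. A peak was assigned to 11 of 83 members, and 2.01% of passing peaks had one against 0.261% of the other candidates (odds ratio 7.84, adjusted p = 9.50e-06, Fisher's exact test). All 11 summits lay upstream of the gene's start, 32 to 1820 bp away with a median of 294 bp. The farthest lay 138 bp from the start of another gene. The strongest were at rpl-3 (III, 3867408 to 3867711, intergenic, signal 163), rpl-15 (IV, 654778 to 655081, intergenic, signal 157), rpl-35 (III, 7854531 to 7854834, intergenic, signal 139) and rps-28 (IV, 1659108 to 1659411, intergenic, signal 108). The first 3 encode proteins of the large ribosomal subunit and the last one of the small subunit. Against the next 2000 candidates in rank the odds ratio was 3.39 (adjusted exact p = 0.0806), and at an IDR of at most 0.001, a limit chosen after the data were seen, it was 9.26 with 3 peaks (adjusted exact p = 0.0590).

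Mitochondrial respiration genes had a peak at 5 of 40 members (0.912% of passing peaks against 0.114%, odds ratio 8.09, adjusted exact p = 0.00634). These included cox-6A (III, 5080667 to 5080970, signal 110, at an snRNA gene) and cox-5B (I, 9788548 to 9788851, intergenic, signal 73), both subunits of cytochrome c oxidase, ucr-11 (I, 6554535 to 6554838, signal 92.9), of the cytochrome bc1 complex, and cyc-2.1, a cytochrome c gene (IV, 4749892 to 4750195, intergenic, signal 77.1), which shares its peak with rpl-20. The summits lay upstream, 25 bp from the start of cox-5B, 905 bp from cox-6A, 1032 bp from cyc-2.1 and 1308 bp from ucr-11. For cyc-2.1 and ucr-11 the start of another gene was closer, at 196 and 42 bp. Histone genes had a peak at 8 of 59 members through 4 peaks (0.730% against 0.0943%, odds ratio 7.79, adjusted exact p = 0.0132). The strongest of these were assigned to his-67 and his-68 (I, 9988792 to 9989095, intergenic) and to his-59 and his-61 (IV, 7486210 to 7486513, intergenic, signal 100.9). The latter summit lay 145 bp upstream of his-61 but 1887 bp upstream of his-59. None of the 4 histone peaks overlapped both replicates' own sets.

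Heat shock and chaperone genes had a peak at 5 of 64 members (1.09% of passing peaks against 0.222%, odds ratio 4.98, adjusted exact p = 0.0132). The test counted 6 peaks, of which 2 overlap each other at dnj-29 and share the same replicate signals. Among them were the J-domain co-chaperone genes dnj-28 (I, 2996215 to 2996518, intergenic, signal 146), dnj-29 (I, 14113081 to 14113384, intergenic, signal 93.1) and dnj-19 (V, 5505100 to 5505403, signal 70.1), and hsp-60, the mitochondrial chaperonin gene (III, 1618979 to 1619282, intergenic, signal 96.3). Ciliary genes had a peak at 4 of 61 members (0.912% against 0.173%, odds ratio 5.32, adjusted exact p = 0.0152): ift-43 (II, 5661686 to 5661989, in an intron of mdt-26, signal 154), dyf-17 (V, 19125916 to 19126219, at a tRNA-Phe gene, signal 126), che-13 (I, 10517100 to 10517403, at a snoRNA gene, signal 110) and daf-19, the regulator of ciliary genes (II, 10169480 to 10169783, intergenic, signal 78.7). The test counted 5 peaks for these 4 members, so not every peak stands for a separate gene. The summits listed lay upstream, 1052 bp from the start of ift-43, 1457 bp from dyf-17, 1666 bp from che-13 and 286 bp from daf-19. The start of another gene was closer for ift-43 (644 bp), che-13 (803 bp) and dyf-17. The ciliary list no longer passed without peaks near small RNA genes (odds ratio 4.96, adjusted exact p = 0.122), with genes as the units (3.58, 0.129), with assignment from 1000 bp upstream (3.88, 0.347) or with the nearest start (1.22, 1). The heat shock list lost its call with genes as the units (odds ratio 3.69, adjusted exact p = 0.0750) and with the nearest start (2.01, 0.534), as did the mitochondrial list with the nearest start (4.96, 0.123).

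The other 20 lists did not pass, and 2 of them, epidermal and cuticle genes (adjusted p = 0.0755) and pharyngeal gland and cuticle genes (adjusted p = 0.107), had an unadjusted Fisher's exact p under 0.05. The homeobox list had a peak at 1 of 102 members and an odds ratio of 0.488 (adjusted exact p = 0.958). That member was lim-8 (III, 6805434 to 6805737, signal 92.7), at a tRNA-Asn gene in its intron; lim-8 is known for its LIM domains rather than a homeodomain. Of 30 panneuronal genes 1 had a peak, unc-44, which encodes an ankyrin of axons (IV, 5982374 to 5982677, exonic, signal 69.5; adjusted exact p = 0.896). Of 147 neuropeptide genes 1 had a peak (odds ratio 0.537, adjusted exact p = 1). The bHLH, neurotransmitter synthesis and transport, Notch pathway, body wall muscle, germline, and basement membrane lists had none, which allows each a share of up to 0.671% (exact 95% limit), and 63 to 259 candidate peaks that did not pass. Their adjusted exact p-values were 0.896 or above. The remaining 9 lists (nuclear hormone receptor, receptor, ion channel, chemoreceptor, axon guidance, Wnt pathway, pharyngeal muscle, intestinal and proteasome genes) had adjusted exact p-values of 0.338 or above. Under alternatives 2 further lists passed. With genes in place of peaks as the units, chemoreceptor genes were fewer among the 429 assigned genes than among genes of the other candidates (2.33% against 6.12%, odds ratio 0.366, adjusted exact p = 0.00358). With each peak given to the nearest start within 5000 bp, pharyngeal gland and cuticle genes passed (odds ratio 3.0, adjusted exact p = 0.0343).

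**Figure D5:**
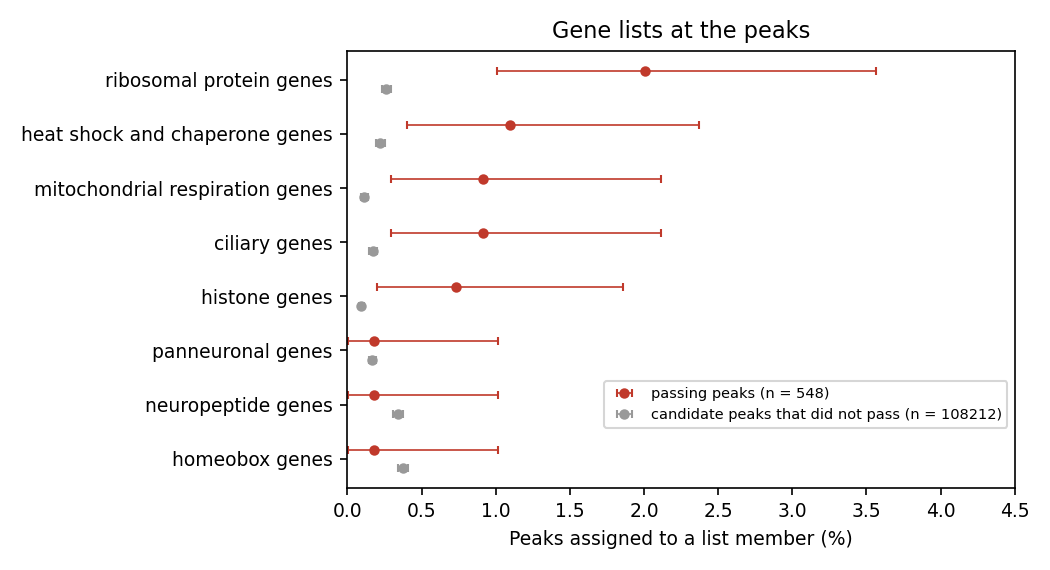
Share of peaks assigned to a member of each list (x axis, percent; bars are exact 95% binomial intervals) for the 548 passing peaks (red) and the 108212 candidates that did not pass (grey), for the 5 lists past the threshold and 3 lists that were not. Ribosomal protein genes stand at 2.01% and 0.261%, and homeobox genes at 0.182% and 0.373%.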

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

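The test of small RNA genes at the removed peaks was chosen after the result was seen; the test of repeated sequence was not. A signal stood in data that the comparisons did not use: 124 candidate peaks of the larger list passed the IDR limit but are absent from the thresholded set. They made up 18.5% of the 672 candidates that passed, their median signal was 157 against 80.1 for the passing peaks, and 19 of the 20 highest signals of the whole list were among them. The highest, 2465, lay in intergenic sequence on chromosome X, 15810958 to 15811196, and the next, 1826, on chromosome X at 11785713 to 11785927; 122 of the 124 were intergenic.

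Small RNA genes are argued against as the source of these peaks, since 0.806% of them (exact 95% interval 0.0204 to 4.41) lay within 250 bp of one, against 35.8% of passing peaks. The removed peak within that distance lay near the rRNA gene rrn-4.2 (V, 17122061 to 17122364, signal 109.5). Sequence repeated in the assembly remains a candidate explanation: in the median removed peak 95.3% of the 31-base words occur more than once, while the median passing peak has 0%. Repeats alone do not mark what was left out, since in 65 passing peaks, or 11.9%, most of the words are repeated too. A filter on repeated regions is therefore a hypothesis only, and none is described in the sources used here. No biological explanation was tested, since the design holds 1 group.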

How the results depend on the processing

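Alternatives with an IDR of at most 0.001, with peaks away from small RNA genes, or with a background matched on GC content were chosen only after seeing the data. The promoter share, small RNA gene share and intergenic share kept their direction and their side of the threshold under every alternative run, with odds ratios of 1.76 to 4.36 apart from 7.74 with starts of all biotypes, 13.0 to 253, and 1.36 to 2.72. Of 78 alternatives for the answers to comparisons, 58 left the result the same, but these include the planned limit of 0.01, which removed no peak and says nothing about stability.

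An IDR of at most 0.001 left 127 peaks, with replicate overlaps of 65.2% and 73.7%, TAATCC at 0.787% of summits (lower than in the flank and now past the threshold), 52 enriched 6-base words and 1 gene list; the histone and mitochondrial respiration lists had no peak left, so their odds ratios were 0. Leaving out a replicate gave 227 to 258 peaks, TAATCC at 1.55% to 2.20%, 121 to 187 words and 1 to 2 lists. Fewer peaks are tested in these settings by construction. The conservative set had TAATCC at 2.38% and past the threshold on the lower side. Away from small RNA genes the odds ratio of X turned to 0.885, and 118 words passed. A window of 51 bp gave 195 words. The number of lists was 0 against the next-ranked candidates, 3 against candidates of the same GC content and 3 with the nearest transcript start within 5000 bp. For the conservative set and the lists the cause was not tested. For X, no excess was left away from small RNA genes, and 276 of the 612 tRNA genes lie on X. Those on X had a peak in 26.8% and those on the autosomes in 23.5% (Fisher's exact test, p = 0.350). Of 60 alternatives for single lists, 23 lost the threshold and 2 reversed; the ribosomal protein list lost it against the next-ranked candidates (odds ratio 3.39) and at an IDR of at most 0.001 (9.26). Depth is unknown, so what it limits cannot be given.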

Other observations

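The tests by tRNA gene class, of other RNA genes, with shuffled windows, of TAATCC at small RNA genes, of small RNA genes at ribosomal protein peaks and with candidates of the same GC content were chosen only after the result was seen. Of the 612 nuclear tRNA genes, 153, or 25% (exact 95% interval 21.6 to 28.6), had a passing summit within 250 bp, against 3 of 209 tRNA pseudogenes, or 1.44% (0.297 to 4.14; odds ratio 22.9, Fisher's exact test, p = 4.20e-18). The share was 26.8% of the 276 tRNA genes on X and 23.5% of the 336 on the autosomes (Fisher's exact test, p = 0.350). By amino acid it ran from 6.45% of 31 valine tRNA genes to 46.2% of 13 cysteine tRNA genes among those with at least 5 genes and a product given, and none differed from the rest after adjustment (lowest adjusted exact p = 0.221). Among snoRNA genes 45 of 346 had a peak, and among snRNA genes 6 did, or 4.65% (exact 95% interval 1.73 to 9.85).

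Several other genes read by RNA polymerase III had a peak. Besides rpr-1, mrpr-1, the gene of the RNase MRP RNA (II, 7200233 to 7200418), had a peak of signal 140, and 3 of the 5 genes of the signal recognition particle RNA had one, srpr-2.2 the strongest with a signal of 152. Of the spliced leader RNA genes, which are read by RNA polymerase II, none of the 12 SL1 genes had a peak, which leaves an exact 95% upper limit of 26.5%, and 2 of the 18 SL2 genes did. Only passing peaks were counted, so a candidate absent from the thresholded set would not show at these genes. The B-box word GTTCGA stood at 89 of 548 summits, where dinucleotide shuffles of the same windows gave a mean of 24.1 ± 4.74 (SD, 500 shuffles; permutation p = 0.00399, the smallest they can give on 2 sides). TAATCC stood at 14 where shuffles gave 16 ± 3.96 (permutation p = 0.758). Among the 352 peaks away from small RNA genes, GTTCGA stood at 9 summits, below the shuffle mean of 15.1 ± 3.71 (permutation p = 0.116).

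For the peaks at small RNA genes, binding through the TAATCC core is argued against: it stood at 2.04% of these summits (upper exact 95% limit 5.14%) and in 4.59% of their flanks. For reads shared between tRNA copies, none of the 22 tRNA genes without a repeated 31-base word carried a peak (0%, upper exact 95% limit 15.4%). Of the other 590, 25.9% did (Fisher's exact test, p = 0.00212). Reads shared between copies would give such a difference. It cannot decide on sharing, because the 22 genes may differ from the others in more than copy number. The 22 genes also did not differ from the tRNA pseudogenes, of which 3 of 209 had a peak. In 37 families of identical tRNA genes the highest candidate signal was 12.3 times the lowest in the median family. Genes with and without a peak were held by 33 families. These family values cannot decide on even sharing, because reads that reach into the flanks of a gene need not be shared. A fixed IDR limit can also separate copies of similar signal. The same candidate can count for different families: a signal of 6.73 was the lowest in a tRNA-Arg and in a tRNA-Cys family. Sharing between copies, even or uneven, stays open for peaks in repeated sequence. In the median of the 196 peaks at small RNA genes, 28.7% of the 31-base words around the summit were repeated. Most words were repeated in only 2 of these peaks. Of the 196 peaks at small RNA genes, 51, or 26%, hold no repeated 31-base word around the summit. These were not split by RNA class, and only 144 passing peaks lay near tRNA genes. The 51 may therefore lie at snoRNA or snRNA genes, and they do not test sharing between tRNA copies. Enrichment at open, highly transcribed loci whatever protein is tagged cannot be told apart from CEH-45 binding, because no untagged or other tagged strain is among the samples; 63.3% of passing peaks lay at a small RNA gene or a protein-coding promoter.

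For the ribosomal protein genes, tRNA, snRNA, snoRNA and rRNA genes beside them are argued against as the whole cause: none of the 11 ribosomal protein peaks lay within 250 bp of such a gene (0%, upper exact 95% limit 28.5%). Other noncoding biotypes were not counted, and the summit at rps-1 lay in a gene of such a biotype. GC content is argued against as well, with an odds ratio of 6.97 against candidates of the same GC content (adjusted exact p = 0.00134). The call was lost against the next 2000 candidates in rank (odds ratio 3.39, adjusted exact p = 0.0806) and at an IDR of at most 0.001 (odds ratio 9.26, adjusted exact p = 0.0590), and over all 12 alternatives the adjusted p ran from 6.71e-08 to 0.0806. Enrichment at transcribed loci in general stays open here too, and no biological explanation was tested because the design holds 1 group.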
